A study of Homo sapiens with 6 samples.

How the data were processed

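Polyadenylated RNA was sequenced from primary human dermal fibroblasts of 1 line in 3 groups of 2 libraries. The groups were untreated cells, cells carrying a doxycycline-inducible lentivirus for mouse wild-type MyoD (WT-MyoD), and cells carrying the same vector for MyoD with the VP64 activation domain at its N-terminus (VP64-MyoD). Per the labels' protocols, the transduced cells were selected with puromycin, grown to confluence and given 3 µg/mL doxycycline until harvest at day 10. The labels do not say whether the untreated cells were transduced, selected or given doxycycline. Libraries were made by transposase tagmentation, which does not mark the strand, so reads of overlapping genes on opposite strands cannot be told apart.

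Per the submitters' processing notes, the authors used CASAVA, Bowtie 0.12.9, DESeq 1.10.1 and the hg19 genome build. The deposited count table holds whole-number read counts per RefSeq transcript, not normalized, for each of the 6 libraries. Every value in it is even, so each read pair was counted as 2. The authors' deposited table of comparisons gives a signal for each group, the group mean of counts divided by size factors. That deposited table also gives log2 fold changes of each MyoD group over untreated, per the file headers. Its adjusted p-values, made by the authors, lie at or under 9.82e-06 for WT-MyoD and 9.95e-06 for VP64-MyoD over its 3135 transcripts. That table was used for a comparison of signs and for the authors' fold changes of the transgene, and entered no test.

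Of 40710 transcript rows, 39324 were matched to a gene symbol by accession through a RefSeq gene table of a newer assembly. A further 517 were matched through GENCODE release 29, and 868 had no symbol. The remaining row was that of the mouse Myod1 transgene. Rows without a symbol held between 0.601% and 0.744% of the counts of a library. No coordinates are given, since the genome builds differ. For 1826 pairs of isoforms with near-equal total counts, the chi-square of isoform by replicate (1 degree of freedom) had a mean between 0.927 and 0.987 in the 3 groups. Reads counted for both isoforms of a pair would give values far under 1. Transcript rows were summed per gene. Genes with near-identical copies can share reads and are uncertain. The library totals lay between 40997586 and 53804224 counts.

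Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM normalization, the filterByExpr filter (minimum count 10, minimum total 15) and the two-sided quasi-likelihood test. The 6 libraries entered 1 fit with 3 residual degrees of freedom. Benjamini-Hochberg adjusted p-values under 0.05 were taken as calls. The fit held 15771 genes beside the mouse transgene. Levels are TMM-scaled CPM, as mean ± SD over 2 libraries. Standard errors are the absolute log2 fold change over the square root of the F statistic. Where all libraries of the lower group had no count, the fold is a lower bound against a floor of 3 read pairs over the group. Floors and intervals cover counting error only. The design text calls the libraries biological duplicates, and all come from 1 line, so p-values measure the spread between cultures of that line.

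The 20 gene lists were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, and with fry, with adjustment over the 60 tests together. The lists cover myogenic transcription factors, sarcomere, excitation-contraction coupling, myoblast fusion, muscle energy metabolism, fibroblast matrix, myofibroblast, TGF-beta and YAP, cardiac muscle, neuronal, adipocyte, cartilage and bone, epithelial with endothelial and blood, cell division, cell cycle inhibitors, Notch, interferon, unfolded protein and amino acid stress, inflammatory secretion, and mitochondrial respiration genes. With a correlation estimated per list, 0 of the 60 camera tests passed, with 22 at an unadjusted p under 0.05, against 35 with the preset correlation and 55 by fry. The estimated correlations ran from -0.141 to 0.446. For the sarcomere list they lay between 0.266 and 0.335, far above the preset 0.01, so its camera p-values at the preset value may be too small. The fry test asks whether the genes of a list move one way on balance and does not compare them with other genes.

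The lists, the tests, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, per comparison, the 10 highest and 10 lowest fold changes among called genes with a mean count of at least 20 in the higher group and no overlap of libraries. It also took up to 4 members of each list with the smallest adjusted p (where none passed, the 2 most abundant), and the measured myogenic transcription factors. Symbols of uncharacterised loci, antisense genes and pseudogenes were passed over among the largest changes, and sex-linked marker genes are not named. Alternatives were DESeq2 1.42.0, limma-voom, RLE size factors, other filters, a replicate block, fits of 2 groups alone and leaving out each library. Counts per read pair, the most abundant transcript per gene, the removal of ribosomal RNA rows and leave-one-out overlaps were added after seeing the data.

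The fit was tested on simulated counts with 200 changed genes per comparison, around 1 mean per gene over all 6 libraries. In the data far more genes were called: 47.9% for WT-MyoD and 63.0% for VP64-MyoD against untreated, and 56.5% for VP64-MyoD against WT-MyoD. The simulation therefore does not test TMM normalization where so many genes change. For WT-MyoD against untreated, over 15530 genes, 77.6% of genes changed 1.5-fold, 86.6% of those changed 2-fold and 98.5% of those changed 4-fold were recovered, with 12 false calls. For VP64-MyoD against untreated, over 15539 genes, the shares were 73.1%, 86.6% and 98.5%, with 17 false calls. For VP64-MyoD against WT-MyoD, over 15525 genes, they were 73.1%, 77.6% and 92.4%, with 13 false calls. False calls were above the nominal 5% of the calls in each comparison. In each, 0 of 19 unchanged lists were called by camera. Genes were simulated independently of each other, whereas the correlation estimated within the real lists reached 0.446. The simulated lists therefore do not test camera on correlated genes. Figures were drawn with matplotlib.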

Results

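The series measured gene expression in human dermal fibroblasts with and without induced MyoD, a transcription factor that can turn fibroblasts into muscle-like cells. The 3 groups were untreated fibroblasts, fibroblasts with WT-MyoD and fibroblasts with VP64-MyoD, with 2 libraries each. Library totals were 53804224 and 48142658 counts in untreated cells, 52860140 and 40997586 counts with WT-MyoD, and 44995262 and 49384350 counts with VP64-MyoD. Ribosomal RNA took 0.663% and 0.803% of the counts in untreated cells, 1.26% and 1.80% with WT-MyoD, and 1.70% and 0.997% with VP64-MyoD. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 3.43 in untreated cells, 13.5 with WT-MyoD and 5.89 with VP64-MyoD.

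The mouse Myod1 transgene stood at 886 ± 180 CPM (SD, n = 2) with WT-MyoD and at 106 ± 13 CPM (SD, n = 2) with VP64-MyoD. It was lower with VP64-MyoD than with WT-MyoD (log2 fold change -3.06, SE 0.25, edgeR adjusted p = 4.3e-08). The untreated libraries held 254 and 46 transgene counts, which is 0.600% and 0.109% of the mean WT-MyoD count. The log2 fold change over untreated was 8.13 for WT-MyoD and 5.07 for VP64-MyoD; without untreated replicate 1 these were 9.72 and 6.66, and without untreated replicate 2 they were 7.44 and 4.37. The untreated levels of KLHL41, TNNI1 and MYBPH rested on 20, 23 and 18 read pairs in replicate 1, the library with more transgene reads. In the authors' deposited table the log2 fold changes of the transgene over untreated were 8.18 and 5.12. The human gene MYOD1 had no count in either untreated library. It stood at 3.49 ± 0.29 CPM (SD, n = 2) with WT-MyoD, at least 54.6-fold higher than untreated, and at 6.92 ± 0.73 CPM (SD, n = 2) with VP64-MyoD, at least 108-fold higher. MYOD1 was higher with VP64-MyoD than with WT-MyoD (log2 fold change 0.99, SE 0.16, edgeR adjusted p = 1.1e-04). These values are of reads counted on the human gene; with WT-MyoD they were 0.399% of the mouse transgene reads, and miscounted transgene reads were not told apart from endogenous ones there, so the fold with WT-MyoD and the fold between the forms cannot be taken as those of the endogenous gene alone.

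**Figure D1:**
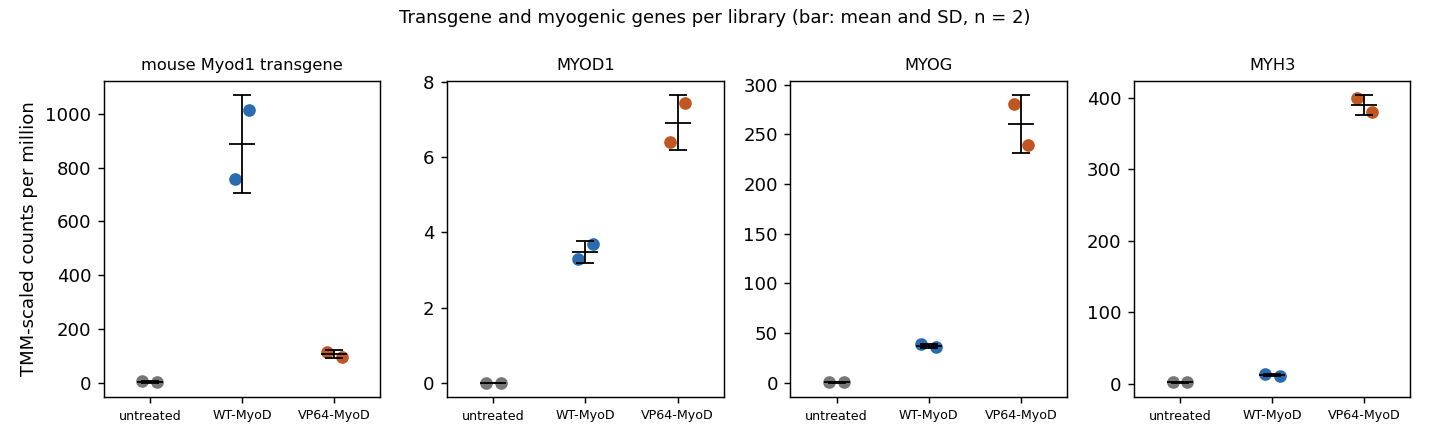
TMM-scaled CPM of the mouse Myod1 transgene and of human MYOD1, MYOG and MYH3 (vertical axes) in the 3 groups (horizontal axes), with a point per library and the mean and SD (n = 2). The transgene is highest with WT-MyoD, at 886 CPM, and MYOG is highest with VP64-MyoD, at 260 CPM.

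The first comparison asked what the wild-type factor did to fibroblasts. With WT-MyoD, MYOG, the myogenic factor of differentiating muscle cells, rose from 0.27 ± 0.066 to 37.2 ± 2.1 CPM (SD, n = 2; log2 fold change 7.06, SE 0.16, edgeR adjusted p = 1.3e-14). The nebulin-binding protein gene KLHL41 rose to 170 ± 21 CPM (log2 fold change 7.96, SE 0.15) and the slow troponin gene TNNI1 to 188 ± 6.7 CPM (log2 fold change 7.94, SE 0.13). Elastin (ELN), a component of fibroblast matrix, fell from 1179 to 135 ± 4.9 CPM (log2 fold change -3.13, SE 0.07, edgeR adjusted p = 9.2e-15). Of 15771 genes, 4054 were higher and 3495 lower than in untreated cells, with 1022 and 161 of them changed over 4-fold.

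Of 57 measured sarcomere genes, 50 rose and 1 fell, with a median log2 fold change of 5.02 (3.93 with genes at 0 in untreated cells set at their bound; camera adjusted p = 4.95e-56; adjusted p = 0.0855 with an estimated correlation). Of 31 genes of excitation-contraction coupling and the neuromuscular junction, 25 rose and 1 fell (camera adjusted p = 7.31e-34; adjusted p = 0.0855 with an estimated correlation). They included the acetylcholine receptor subunits CHRNA1, at 461 ± 38 CPM, and CHRNB1, at 155 ± 3.4 CPM. Of 31 genes of myoblast fusion and muscle membrane, 23 rose and 5 fell (camera adjusted p = 8.94e-24; adjusted p = 0.0855 with an estimated correlation), with the laminin receptor subunit ITGA7 at 520 ± 37 CPM. Of 27 muscle energy genes, 18 rose and 2 fell (camera adjusted p = 7.41e-07; adjusted p = 0.226 with an estimated correlation). Creatine kinase CKM rose to 14.4 ± 2.6 CPM (log2 fold change 6.39, SE 0.23). Of 26 myogenic transcription factors, 15 rose and 5 fell (camera adjusted p = 9.74e-05; adjusted p = 0.164 with an estimated correlation). HES6, MEF2C and PITX3 rose by log2 fold changes of 5.17, 1.61 and 6.29, whereas MSC, a repressor of myogenic factors, fell by 1.72 on the log2 scale.

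Cell division genes rose with WT-MyoD in 45 of 45 measured members (median log2 fold change 2.26, camera adjusted p = 8.38e-46; adjusted p = 0.0855 with an estimated correlation). TOP2A, a topoisomerase of dividing cells, went from 26.9 ± 1.1 to 160 ± 2.7 CPM. Interferon response genes rose in 28 of 30 members and fell in 1 (median log2 fold change 2.79, camera adjusted p = 6.45e-23; adjusted p = 0.130 with an estimated correlation). The antiviral genes OAS2 and IFI6 stood at 74.5 ± 2.9 and 82.3 ± 4.1 CPM, against 1.94 ± 0.082 and 3.20 ± 0.35 CPM in untreated cells. Of 53 fibroblast matrix and identity genes, 33 fell and 13 rose (camera adjusted p = 4.2e-08; adjusted p = 0.199 with an estimated correlation); TNC fell by 1.92 on the log2 scale and S100A4 rose by 2.02. Of 19 myofibroblast genes, 11 fell and 3 rose (camera adjusted p = 3.2e-05; adjusted p = 0.0855 with an estimated correlation), with the smooth muscle actin ACTA2 at 216 ± 10 against 555 ± 25 CPM. Of 22 unfolded protein and amino acid stress genes, 15 fell and 2 rose (camera adjusted p = 1.48e-12; adjusted p = 0.0855 with an estimated correlation), and TRIB3 fell by 2.74 on the log2 scale.

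Of 15 neuronal genes past the filter, among 32 listed, 7 rose and 0 fell with WT-MyoD (camera adjusted p = 0.00197, or 0.163 with an estimated correlation). Of 17 Notch genes, 8 rose and 4 fell (camera adjusted p = 0.00164; adjusted p = 0.1205 with an estimated correlation), with HEYL at 124 ± 3.3 CPM against 0.36 ± 0.12 CPM. That Notch call ended without VP64-MyoD replicate 1 (camera adjusted p = 0.0953), without VP64-MyoD replicate 2 (0.0859) and with no filter on low counts (0.0859), in a range over the alternatives from 4.1e-04 to 0.1205. The TGF-beta and YAP (camera adjusted p = 0.0551), cardiac (0.242), adipocyte (0.271), cartilage and bone (0.0826), epithelial, endothelial and blood (0.806), cell cycle inhibitor (0.138), inflammatory (0.906) and mitochondrial (0.701) lists did not pass. Of these, the TGF-beta and YAP list passed without untreated replicate 1 (camera adjusted p = 0.0340) and with no filter (0.0357), in a range from 0.0340 to 0.318. The cartilage and bone list passed without untreated replicate 1 (camera adjusted p = 0.0438) and without WT-MyoD replicate 1 (0.0437), in a range from 0.0437 to 0.378. The cell cycle inhibitors passed without VP64-MyoD replicate 1 (camera adjusted p = 0.0356), without VP64-MyoD replicate 2 (0.0360) and with no filter (0.0180), in a range from 0.0180 to 0.307. Median, mean and test differed in sign for the inflammatory list (medians and means above 0, test downward) and the cartilage and bone list (mean above 0, median and test downward). Adjusted over the list alone, 26 excitation-contraction, 14 fibroblast matrix, 5 myofibroblast and 11 cell cycle inhibitor genes were higher. Adjusted over the list alone, 9 mitochondrial genes were higher and 0 lower, against 12 and 1 over all genes. For the other lists the counts were the same both ways. Since the untreated cells may not have had the vector, selection or doxycycline, these differences hold the effect of all of them together. The labels give no harvest day for the untreated cells, so time in culture and cell density may differ as well. The same limits hold for VP64-MyoD against untreated cells.

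The second comparison set VP64-MyoD against untreated cells. DES, the intermediate filament of muscle, went from 1.34 ± 0.092 to 1210.1 ± 150 CPM (SD, n = 2; log2 fold change 9.81, SE 0.13, edgeR adjusted p = 5.6e-17). MYOG reached 260 ± 29 CPM (log2 fold change 9.86, SE 0.15), and CACNG1, a subunit of the muscle calcium channel, stood at 55.1 ± 1.8 CPM, at least 862-fold higher. PI16, a gene of fibroblasts, went from 600 ± 29 to 4.98 ± 0.25 CPM (log2 fold change -6.91, SE 0.10, edgeR adjusted p = 5.8e-17). Of 15771 genes, 5205 were higher and 4738 lower, with 1226 and 292 changed over 4-fold.

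With VP64-MyoD, 52 of 57 sarcomere genes rose and 0 fell (median log2 fold change 8.75, or 7.08 with genes at 0 in untreated cells at their bound; camera adjusted p = 3.99e-123; adjusted p = 0.0855 with an estimated correlation). ACTN2, an actin crosslinker of the Z-disc, reached 295 ± 29 CPM. Of 31 excitation-contraction and neuromuscular genes, 28 rose and 2 fell (camera adjusted p = 9.07e-50; adjusted p = 0.0855 with an estimated correlation). Of 26 myogenic transcription factors, 20 rose and 5 fell (camera adjusted p = 1.64e-13; adjusted p = 0.0855 with an estimated correlation), with MEF2C at 93.5 ± 1.7 CPM and TEAD4 at 54.7 ± 1.6 CPM. Of 31 fusion and membrane genes, 21 rose and 7 fell (camera adjusted p = 1.51e-22; adjusted p = 0.0927 with an estimated correlation), and MYMK, which drives myoblast fusion, reached 200 ± 27 CPM. Of 27 muscle energy genes, 22 rose and 2 fell (camera adjusted p = 5.87e-09; adjusted p = 0.188 with an estimated correlation), with CKM at 156 ± 17 CPM.

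Cell division genes rose in 45 of 45 members (median log2 fold change 1.78, camera adjusted p = 2.35e-18; adjusted p = 0.0897 with an estimated correlation). Of 53 fibroblast matrix genes, 38 fell and 7 rose (camera adjusted p = 1.84e-08; adjusted p = 0.199 with an estimated correlation), with ELN at 24.0 ± 1.0 CPM and FBLN1 at 154 ± 4.6 against 861 ± 12 CPM. Of 17 Notch genes, 12 rose and 3 fell (camera adjusted p = 8.31e-07; adjusted p = 0.0855 with an estimated correlation), and JAG2, a Notch ligand, rose by a log2 fold change of 6.07. Of 34 mitochondrial respiration genes, 29 rose and 0 fell (median log2 fold change 0.45, camera adjusted p = 0.0169; adjusted p = 0.622 with an estimated correlation). Of 15 neuronal genes past the filter, among 32 listed, 12 rose and 1 fell (camera adjusted p = 0.00136, or 0.137 with an estimated correlation). Among those that rose, DCX and MYT1L stood at only 0.34 and 0.39 CPM with VP64-MyoD. Of 16 cell cycle inhibitors, 8 rose and 4 fell (camera adjusted p = 0.0393; adjusted p = 0.199 with an estimated correlation), and the call ended without untreated replicate 2 (camera adjusted p = 0.0524) and with no filter (0.106), in a range from 0.0393 to 0.199. CDKN1C in that list rose to 141 ± 11 CPM.

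Interferon response genes did not pass as a list with VP64-MyoD (17 rose and 6 fell, camera adjusted p = 0.159), but passed without VP64-MyoD replicate 2 (camera adjusted p = 0.0198) and with no filter (0.0239), in a range from 0.0198 to 0.725. USP18 rose by a log2 fold change of 3.14 and IFIT2 fell by 2.33 on the log2 scale. The myofibroblast (camera adjusted p = 0.393), TGF-beta and YAP (0.871), cardiac (0.233), adipocyte (0.466), cartilage and bone (0.719), epithelial, endothelial and blood (0.466), unfolded protein (0.268) and inflammatory (0.817) lists did not pass. Median, mean and test differed in sign for the myofibroblast list (median above 0, mean and test downward), the cartilage and bone list (median below 0, mean and test upward) and the epithelial, endothelial and blood list (mean above 0, median and test downward). Adjusted over the list alone, 23 energy, 13 Notch and 30 mitochondrial genes were higher, 6 cartilage and bone genes and 5 of the epithelial, endothelial and blood genes were lower, and other counts were the same.

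The direct comparison of VP64-MyoD with WT-MyoD asked how the forms differed, with the same vector, selection and doxycycline per the labels' protocols. Transgene RNA also differed between them (log2 fold change -3.06), so no difference given here separates the domain from the amount of transgene. MYH3, the embryonic myosin heavy chain, was higher with VP64-MyoD, at 390 ± 14 against 12.0 ± 1.6 CPM (SD, n = 2; log2 fold change 5.02, SE 0.09, edgeR adjusted p = 9.4e-15), and the troponin TNNC2 at 61.4 ± 5.7 against 0.56 ± 0.11 CPM (log2 fold change 6.74, SE 0.14). MYOG was higher by a log2 fold change of 2.81 (SE 0.08, edgeR adjusted p = 4.8e-13). MX1, an antiviral gene, was lower, at 9.85 ± 3.5 against 137 ± 2.2 CPM (log2 fold change -3.81, SE 0.15, edgeR adjusted p = 9.7e-12). Of 15771 genes, 4471 were higher and 4447 lower, with 601 and 352 changed over 4-fold.

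Of 57 sarcomere genes, 51 were higher with VP64-MyoD and 0 lower (median log2 fold change 2.81, camera adjusted p = 5.25e-78; adjusted p = 0.0855 with an estimated correlation). Of 31 excitation-contraction and neuromuscular genes, 24 were higher and 1 lower (camera adjusted p = 1.62e-20; adjusted p = 0.0855 with an estimated correlation), with the calcium pump ATP2A1 at 88.2 ± 13 against 4.29 ± 0.079 CPM. Of 26 myogenic transcription factors, 18 were higher and 2 lower (camera adjusted p = 1.17e-11; adjusted p = 0.0855 with an estimated correlation), with HES6 higher by a log2 fold change of 3.06. Fusion and membrane genes were higher in 15 and lower in 9 of 31 (camera adjusted p = 0.00325; adjusted p = 0.424 with an estimated correlation); MYMK was higher and CDON, a receptor of myoblasts, lower, by log2 fold changes of 2.36 and -1.98. Muscle energy genes were higher in 17 and lower in 3 of 27 (camera adjusted p = 0.00774; adjusted p = 0.433 with an estimated correlation).

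Interferon response genes were lower with VP64-MyoD in 27 and higher in 2 of 30 (median log2 fold change -2.09, camera adjusted p = 1.61e-21; adjusted p = 0.126 with an estimated correlation). Cell division genes were lower in 34 and higher in 1 of 45 (median log2 fold change -0.49, camera adjusted p = 2.46e-05; adjusted p = 0.199 with an estimated correlation), with TOP2A at 92.3 ± 7.2 CPM. Unfolded protein and amino acid stress genes were higher in 20 and lower in 1 of 22 (camera adjusted p = 1.04e-09; adjusted p = 0.0897 with an estimated correlation). Asparagine synthetase ASNS in that list stood at 137 ± 4.1 against 38.7 ± 4.6 CPM. In untreated cells ASNS stood at 141 CPM, and VP64-MyoD was not called different from them (log2 fold change -0.04, edgeR adjusted p = 0.64). Myofibroblast genes were higher in 10 and lower in 4 of 19 (camera adjusted p = 0.0012; adjusted p = 0.114 with an estimated correlation), with ACTA2 at 650 ± 11 CPM and TPM1 higher by a log2 fold change of 1.81. Notch genes were higher in 13 and lower in 3 of 17 (camera adjusted p = 0.00133; adjusted p = 0.126 with an estimated correlation), mitochondrial genes higher in 26 and lower in 3 of 34 (camera adjusted p = 0.00946; adjusted p = 0.594 with an estimated correlation). Cartilage and bone genes were higher in 8 and lower in 4 of 12 (camera adjusted p = 0.00325, or 0.130 with an estimated correlation). COL11A1 was higher and ACAN lower, by log2 fold changes of 2.33 and -4.15. COL11A1 stood at 430 CPM with VP64-MyoD and 85.8 CPM with WT-MyoD, both under the 688 CPM of untreated cells. ACAN stood at 15.4 CPM in untreated cells, 42.4 CPM with WT-MyoD and 2.40 CPM with VP64-MyoD. Against untreated cells the list did not pass with VP64-MyoD (camera adjusted p = 0.719).

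Genes at 0 in both WT-MyoD libraries and raised by VP64-MyoD included the potassium channel KCNQ1, at 5.17 ± 0.46 CPM and at least 84.3-fold higher, and the calcium-binding protein PVALB, at least 55.1-fold higher. TNXB, a matrix glycoprotein whose gene has a near-identical partial copy that leaves its counts uncertain, fell from 582 ± 170 to 8.26 ± 0.62 CPM (log2 fold change -6.14, SE 0.17). The fibroblast matrix list did not pass (camera adjusted p = 0.122), but did without WT-MyoD replicate 1 (camera adjusted p = 0.0368), in a range from 0.0368 to 0.622. The TGF-beta and YAP (0.0662), cardiac (0.559), neuronal (0.449), adipocyte (0.861), epithelial, endothelial and blood (0.264), cell cycle inhibitor (0.245) and inflammatory (0.906) lists did not pass either. Median, mean and test differed in sign for the cardiac list and the cell cycle inhibitors (median below 0, mean and test upward) and for the adipocyte list (mean above 0, median and test downward). Adjusted over the list alone, 16 fusion genes were higher and 10 lower, and 4 energy, 36 cell division and 11 inflammatory genes were lower. On that scale 6 cell cycle inhibitors and 27 mitochondrial genes were higher, and other counts were the same.

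**Figure D2:**
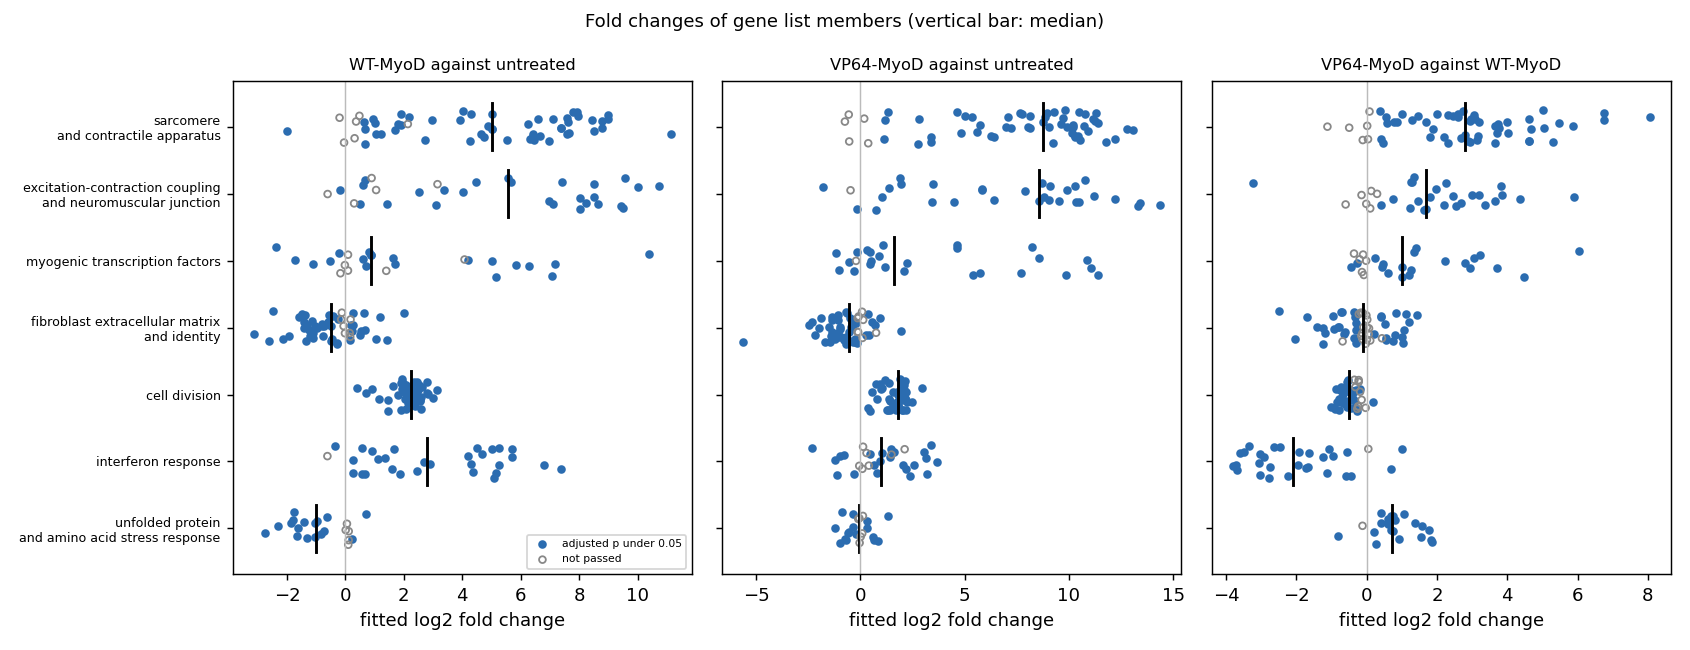
Fitted log2 fold changes (horizontal axes) of the members of 7 gene lists (vertical axis) in the 3 comparisons, with filled points for adjusted p under 0.05 and a bar at the median; the horizontal scales differ between panels. The sarcomere median moves from 5.02 with WT-MyoD to 8.75 with VP64-MyoD, and the interferon median in the direct comparison lies at -2.09.

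Both MyoD forms were set against the same untreated libraries. They shared 2767 higher genes and 2303 lower genes, MYOG and ELN among them, where independent lists would share 1338 and 1050. In 20 simulations of unchanged groups, 0.05 and 0 genes were shared on average. With no change simulated, few calls could arise, so these values do not show how shared controls act among changed genes. Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.792 (0.513 simulated) and a covariance of 2.01 (0.0206 simulated). Part of the excess may come from the shared controls, which were too few to split. Among the 7549 genes called with WT-MyoD, 47.1% lay further from 0 with VP64-MyoD (95% Wilson interval 46.0 to 48.2), and among the 9943 called with VP64-MyoD 76.5% did (75.7 to 77.4). Each choice favours its own group. The intervals count genes as independent, which they are not, so they are too narrow. In several fits without 1 library the shares fell outside them. All 3135 transcripts of the authors' deposited table had the sign of the gene-level fit for WT-MyoD, and 3134 for VP64-MyoD. That table holds only transcripts with very small adjusted p-values in both comparisons, made from the same libraries. The shared signs therefore follow from that choice and are no independent evidence.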

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

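All tests of explanations in this part were chosen after the results were seen. The MyoD forms differed in direction for 497 genes that were higher with WT-MyoD and lower with VP64-MyoD than in untreated cells, and for 308 genes with the opposite pattern. All 805 also differed in the direct test of VP64-MyoD against WT-MyoD (edgeR), which follows from how they were chosen, since the calls share 1 fit and the same controls, and is no independent evidence. More genes changed alike, with 2767 higher and 2303 lower with both forms than in untreated cells.

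Transgene reads appeared in untreated cells, with 254 counts of mouse Myod1 in replicate 1 and 46 in replicate 2. One candidate explanation is carry-over of whole WT-MyoD libraries, which would bring muscle transcripts in the same fraction. In replicate 1, 0 of 14 sarcomere and excitation-contraction genes lay below the need at a Bonferroni-adjusted one-sided Poisson p under 0.05. CHRNA1 (49 read pairs against 68.2 needed), TNNI1 (23 against 27.7), KLHL41 (20 against 25.3) and TNNT2 (16 against 24.3) lay below it in value. ASPH, TPM3, CACNA2D1 (1335 against 12.0), JPH2 (1255 against 11.7), ABLIM3 (694 against 15.7) and TTN (292 against 26.9) were far above it. Genes that high in untreated cells would lie above it with or without carry-over, so the 0 of 14 is a weak test. Over 49 genes chosen without replicate 1, the reads summed to 110% of the need (95% bootstrap interval 76.9 to 155). Of them, 32 lay below it in value, with no test per gene. The genes' own reads in untreated cells were not subtracted. Among them, ACTC1 held 369 read pairs against 158.5 needed in replicate 1, and 236 against 28.7 needed in replicate 2. The sum therefore cannot tell carry-over from the genes' own expression, and the source in replicate 1 stays open. In replicate 2 only 3 genes had enough reads, with 0 below, and carry-over and vector in these cells cannot be told apart.

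Human MYOD1 reads could be mouse transgene reads counted on the human gene. If all human reads with WT-MyoD were such reads, at 0.399% of the mouse reads, they would supply 6.05% of the MYOD1 reads with VP64-MyoD. That argues against this source for most MYOD1 reads with VP64-MyoD. For WT-MyoD, endogenous and miscounted reads cannot be told apart, since no group carries the transgene without possible human MYOD1.

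Interferon response genes were lower with VP64-MyoD than with WT-MyoD in 27 of 30 members. Vector, selection and doxycycline were the same for both groups per the labels' protocols, but the 27 members are the pattern itself and no other value tests unequal exposure, so that source cannot be told apart from the MyoD forms. The amount of transgene RNA, with a log2 fold change of -3.06, may play a part. It cannot be told apart from the VP64 domain itself, since each form was measured at 1 dose.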

How the results depend on the processing

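Counts per read pair, the most abundant transcript per gene, removal of ribosomal RNA and leave-one-out overlaps were chosen after the results were seen. Leaving out a library assumes that the sample left alone varies like the other groups. All 6 counts of higher and lower genes, and both overlaps, stayed within 1.5 times under each of the alternatives run for them; the replicate block gave 4028 higher and 3496 lower genes for WT-MyoD against untreated. Under the block the Notch call for WT-MyoD was lost (camera adjusted p = 0.109) and the cell cycle inhibitors passed (0.0352). Replicate numbers did not pair the samples (correlations of deviations 0.031, 0.022 and 0.0071). DESeq2 gave 3663 higher and 2993 lower genes for WT-MyoD against untreated. The main fit pools the spread over groups whose replicates varied unequally. Fits of the 2 groups alone called 6988 genes for WT-MyoD against untreated, where the main fit called 7549. For VP64-MyoD against untreated such a fit called 10647, where the main fit called 9943. The number of list tests that passed fell from 35 to 0 with an estimated correlation, where 3 residual degrees of freedom limit the test, and lay between 34 and 37 without 1 library. The share further from 0 with VP64-MyoD ran from 43.8% to 48.3% without 1 library among genes called with WT-MyoD, and from 73.7% to 79.1% among genes called with VP64-MyoD; fewer samples enter these fits. Among 366 named gene values, 14 changed side of the threshold under some alternative and 35 moved over 1.5-fold without 1 library; the cause was not tested. Among 60 list values, 2 calls were lost and 5 gained under alternatives other than the estimated correlation.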

Other observations

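Genes outside the muscle lists also differed between VP64-MyoD and WT-MyoD. CDKN1C, an inhibitor of cyclin-dependent kinases, stood at 141 ± 11 CPM with VP64-MyoD and 5.78 ± 0.32 CPM with WT-MyoD (log2 fold change 4.60, SE 0.09). STMN2, a neuronal microtubule regulator, stood at 63.1 ± 4.6 against 9.38 ± 0.32 CPM, and the bone phosphatase ALPL at 30.7 ± 0.11 against 3.02 ± 0.22 CPM. The keratin-associated gene KRTAP16-1 and the epidermal gene SPRR2G had no count with WT-MyoD and were at least 30.8-fold and 44.9-fold higher with VP64-MyoD. The cytokines IL11 and LIF were higher with VP64-MyoD than with WT-MyoD by log2 fold changes of 2.64 and 2.62. The mitochondrial superoxide dismutase SOD2 was lower in the same comparison, by -1.92. The inflammatory list that holds them had 8 members higher and 10 lower, down to a log2 fold change of -5.17. It did not pass (camera adjusted p = 0.906).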
